A study of Homo sapiens with 24 samples.

How the data were processed

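Total RNA from HB2 cells 48 h after transfection with 50 nM siRNA was labelled with biotin and read on Illumina bead arrays, 24 in all: 6 replicates each of a control siRNA and of siRNAs against exons 1, 7 and 9 of GNG12-AS1, with groups taken from the labels. The deposited non-normalized table holds log2 intensities, 1 value per probe and array, with no normalization between arrays. The deposited series matrix of the authors holds log2 intensities that share 1 distribution on all arrays (medians 7.56) and the rank order of the non-normalized values, as quantile normalization gives. The tools behind both are not given in the sources used here. Detection p-values and control probes were not used here.

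Of 47231 probes 47228 had a value on all arrays, 30113 had 1 gene symbol, 8 had several and 17110 had none. For 30074 the symbol was matched by gene number to the current RefSeq names. The non-normalized values were returned to the linear scale, background corrected with limma's neqc (normexp with an offset of 16), quantile normalized and returned to log2, in limma 3.58.1 on R 4.3.3. In place of negative control probes, 437 probes of olfactory receptor genes served as surrogates of background (array medians 7.07 to 7.44). A probe was kept when its surrogate detection p was below 0.05 on at least 6 arrays, which left 19372 probes, 14526 of them named. The brightest kept probe stood for each gene, which gave 11006 genes; values of other probes are given for some of the named genes. A group whose arrays lay below background gave only a bound, computed against the lowest value above background on each array. Where a named gene was above background on only 1 or 2 arrays of a group (MMP9, LOX and RNU4-1), values under that level were set to it as well.

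A linear model with 1 mean per group was fitted over all 24 arrays with limma's lmFit and eBayes, and the 6 comparisons between groups were tested two-sided, with Benjamini-Hochberg adjustment over genes at 0.05. The model, the alternatives, 29 gene lists and the rule for named genes were set before the data were examined. The rule takes the 8 largest rises and falls against control among genes past the threshold whose 6 siRNA arrays lie on 1 side of the control mean, the 8 rises and falls shared by all 3 siRNAs with the largest smallest change, the 5 largest differences each way between siRNAs, the neighbours of the locus, and up to 4 members of smallest adjusted p from each list that passed, and from MET signalling and the interferon response in any case. Lists with at least 3 genes tested (28) were tested with limma's camera at a preset correlation of 0.01, adjusted over lists and the 3 siRNAs, beside camera with an estimated correlation and fry. Genes shared by siRNAs and the correlation of fold changes were set beside 100 simulated draws of unchanged groups against shared controls.

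The steps were tested on simulated data with 50 changed genes per size: 26% were recovered at a log2 change of 0.3, 64% at 0.5 and 100% at 1 and 2, while 9 of 10806 unchanged genes were called. The simulated values were independent between genes and between arrays. These rates therefore leave out genes that vary together and differences between column sets or replicate numbers, which the real arrays have. Alternatives were a block or random effect for the replicate number, no background correction, median scaling, cyclic loess, the authors' normalized values, no detection filter, a stricter one (p below 0.01 on all arrays), the mean of a gene's probes, array weights, the arrays of the compared groups alone, a 1.5-fold minimum, and leaving out 1 array at a time. After the data were seen, the column set of the table (the first and last 12 array columns) as a block, each set alone, both blocks together, the replicate block with an estimated correlation for the lists, differences and permutations of interferon means within the same number, list tests between siRNAs, bounds for the partly detected genes and list counts with 1 array left out were added. Values of a group of 6 arrays were checked with Dixon's test at 0.625, and 100 random splits of the arrays were drawn for each count. A block for the chip was not run, since the columns name no chip, and sequence matches to the siRNAs were not run, since no untranslated-region sequences were used here.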

Results

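HB2 cells, an immortalized human mammary epithelial line, were transfected for 48 h with 50 nM of a control siRNA or of an siRNA against exon 1, exon 7 or exon 9 of GNG12-AS1, a long noncoding RNA gene that lies antisense to GNG12 on chromosome 1. RNA from 6 replicates of each of the 4 groups was read on 24 Illumina bead arrays. By the sample titles, each replicate number stands for 1 experiment with an array of every group, though the titles number most of the experiments differently. The main fits leave this number out, so their standard errors and p-values count variation between numbers as noise. Fits with it called more genes, as given with the alternatives. Before normalization the array medians ranged from 7.41 to 7.74 on the log2 scale. Between 34.5% and 39.8% of probes lay above background on each array. After filtering, 11006 genes were tested. The arrays stood in 2 sets of columns in the table, each with 3 arrays of every group, and the second principal component (12.9% of the variance) separated the sets completely. Each comparison is therefore also given with the column set as a block and within each set. Values are log2 fold changes ± standard error of the model, with n = 6 arrays per group, and the number of arrays limits their precision.

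The first question was whether the siRNAs lowered their target and whether neighbouring genes moved with it. No probe carried the name GNG12-AS1 (0 in the annotation), so the knockdown was not checked on the arrays. DIRAS3, an imprinted gene of the RAS family next to GNG12-AS1, had 2 probes, above background on 5 and on 0 of the 24 arrays. No difference could be detected at this signal. GNG12, a G-protein gamma subunit, differed from control by 0.15 ± 0.12 under the exon 1 siRNA (adjusted p = 0.506), by -0.17 ± 0.12 under exon 7 (adjusted p = 0.667) and by 0.04 ± 0.12 under exon 9 (adjusted p = 0.939). Of 21 listed neighbours 11 were measured. Against control limma called 0 of the 33 tests over all genes and 0 adjusted over the list alone, while 5 had an unadjusted p below 0.05. The nearest to a call was WLS, which carries Wnt proteins to the cell surface, at 0.31 ± 0.10 under exon 9 (adjusted p = 0.0878; 0.0511 over the list alone) and 0.26 ± 0.10 under exon 1 (adjusted p = 0.102). With the column set as a block WLS passed under both siRNAs (adjusted p = 0.0424 under exon 1 and 0.0316 under exon 9), and without control replicate 5 it passed under exon 9 (adjusted p = 0.0452). Its 4 other probes gave -0.07 to 0.29 under exon 1 and 0.19 to 0.41 under exon 9. Some neighbours did differ between siRNAs. Of the 11, 2 were higher and 1 lower under exon 1 than under exon 7. Under exon 7, 1 was higher and 1 lower than under exon 9, while 0 differed between exons 1 and 9. As a set the neighbours gave adjusted p = 0.340 by camera in both comparisons with exon 7.

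**Figure D1:**
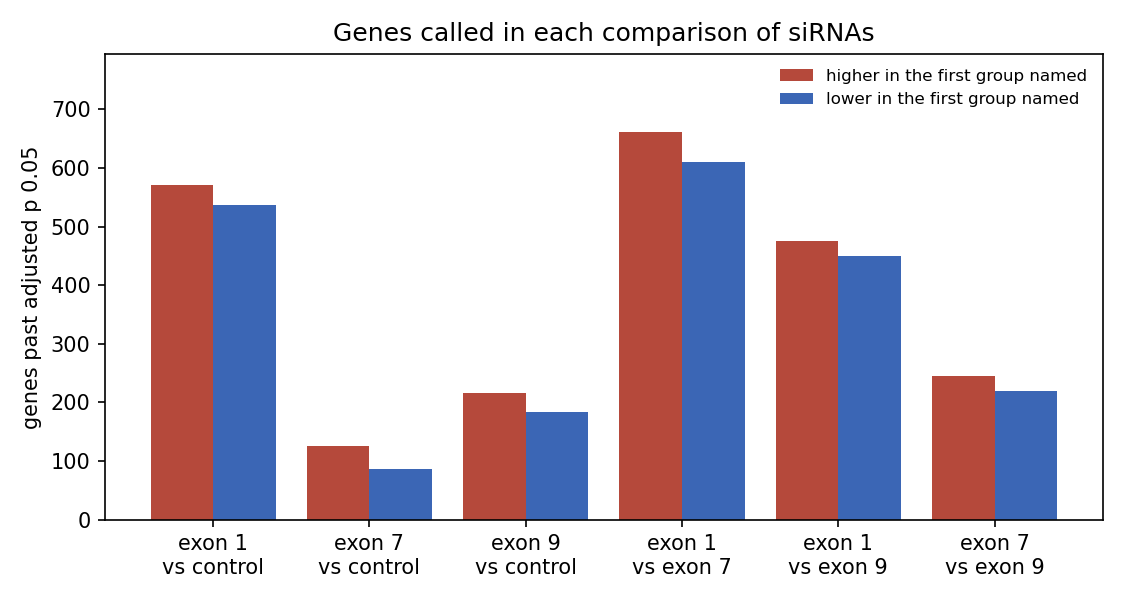
Number of genes higher and lower at an adjusted p below 0.05 in each of the 6 comparisons, 6 arrays against 6. The exon 1 siRNA differed from control in 1108 genes, the exon 9 siRNA in 400 and the exon 7 siRNA in 212.

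Under the exon 1 siRNA KATNAL1, related to the microtubule-severing katanins, rose 3.35-fold (1.74 ± 0.21, adjusted p = 5.61e-06; above background on 5 of 6 control arrays). LZTFL1, a regulator of ciliary protein traffic, rose 3.30-fold (1.72 ± 0.18, adjusted p = 7.66e-07; above background on 4 of 6 control arrays). The cyclin CCND3 rose by 1.28 ± 0.10 (adjusted p = 1.72e-08) and the kinase SGK1 by 1.29 ± 0.15 (adjusted p = 3.55e-06; 1.43 and 1.34 on other probes). WSB1, a part of a ubiquitin ligase, rose by 1.43 ± 0.15, the homeobox gene IRX3 by 1.35 ± 0.30 and the mitochondrial phosphatase PTPMT1 by 1.25 ± 0.11. MMP9, a matrix metalloproteinase, was at least 1.86-fold higher (adjusted p = 4.71e-06), with a probe above background on 6 exon 1 arrays and only 1 control array. FAM117B fell 2.64-fold (-1.40 ± 0.12, adjusted p = 3.04e-08). The ubiquitin ligase WWP1 fell 2.50-fold (-1.32 ± 0.12, adjusted p = 6.78e-08) and the cold-shock protein YBX3 2.27-fold (-1.18 ± 0.11, adjusted p = 1.42e-07). SCML1, MED11, VPS9D1-AS1 and LIMS1 fell by 1.34, 1.21, 1.19 and 1.17 on the log2 scale. PLEKHA3 was at least 1.30-fold lower, since it was above background on 0 of 6 exon 1 arrays. Second probes gave -0.80 for FAM117B, -0.33 for SCML1 and -0.63 for LIMS1.

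In the groups fixed beforehand, 9 of 15 measured mesenchymal markers rose under the exon 1 siRNA and 0 fell (10 rose adjusted over the list alone), with a median of 0.44 (0.39 and 0.50 in the column sets). The actin-binding TAGLN rose by 1.04 ± 0.20, the collagen cross-linking enzyme LOX at least 1.88-fold (above background on 2 of 6 control arrays), and the transcription factors SNAI2 and TWIST1 by 0.66 ± 0.10 and 0.63 ± 0.12. This list passed camera (adjusted p = 6.25e-07) and held at adjusted p = 0.0137 with an estimated correlation. The 8 fibroblast markers measured, of which COL1A1, COL1A2 and THY1 are also on that list, all lay above control, from 0.03 to 0.53. By limma 0 of these 8 passed (1 at an unadjusted p below 0.05; 0 over the list alone), and as a set they gave adjusted p = 0.170 by camera and 0.0133 by fry. Of 9 basal mammary markers 4 rose (5 over the list alone; median 0.42, adjusted p = 0.00310), OXTR by 0.69 ± 0.16 and CAV1 by 0.31 ± 0.07. The list gave adjusted p = 0.192 with an estimated correlation. Of 27 migration and invasion genes 7 rose (9 adjusted over the list alone; median 0.14, adjusted p = 0.00918), MMP9 and the actin-bundling FSCN1 (0.42 ± 0.06) among them. The list had adjusted p = 0.485 with an estimated correlation. Cell migration and MET were themes of the study's published account, so these lists are not independent evidence of their direction. Of 15 glucocorticoid targets 3 rose (5 over the list alone; adjusted p = 0.00261), with SGK1 and TSC22D3 (0.64 ± 0.08). This list gave adjusted p = 0.192 with an estimated correlation. Of 28 autophagy and lysosome genes 5 rose (5 over the list alone; adjusted p = 0.00261), such as GABARAPL1 and CTSD, each by 0.38 ± 0.09. That list gave adjusted p = 0.233 with an estimated correlation. Among p53 targets 3 of 22 rose (4 over the list alone; adjusted p = 0.0131, and adjusted p = 0.643 with an estimated correlation), but 0 rose without exon 1 replicate 2 or without control replicate 6. Among cholesterol synthesis genes 3 of 18 rose (3 over the list alone; adjusted p = 0.0317), MVK by 0.60 ± 0.16. Without control replicate 1, 4 or 6 or exon 1 replicate 3 or 6 only 1 of them rose, and LSS was lost when probes were averaged (adjusted p = 0.372). As a set these gave adjusted p = 0.662 with an estimated correlation. Among TGF-beta targets 2 of 19 rose (7 rose and 1 fell over the list alone; adjusted p = 0.0386), TGFBI by 0.44 ± 0.10. The set gave adjusted p = 0.662 with an estimated correlation. Of 32 interferon response genes 2 fell (2 over the list alone; median -0.21, adjusted p = 0.0337), IFIT2 (-0.69 ± 0.17) and OASL (-0.92 ± 0.24). The interferon list had adjusted p = 0.986 with an estimated correlation. The interferon medians were -0.40 and -0.04 in the column sets, and OASL (-0.39 on a second probe) lost its call when probes were averaged (adjusted p = 0.0551). Leaving out 1 array gave 7 to 9 rises among mesenchymal, 3 to 6 among basal, 4 to 10 among migration, 2 to 4 among glucocorticoid, 3 to 6 among autophagy and 2 to 5 among TGF-beta genes.

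In all, 1108 genes changed under the exon 1 siRNA, 571 higher and 537 lower (29 and 20 of them at least 2-fold). With the column set as a block 1273 changed, and within the sets 233 and 97 did. A fit on the 12 arrays of the 2 groups alone called 684.

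Under the exon 7 siRNA JOSD1, a deubiquitinase, fell 2.98-fold (-1.57 ± 0.09, adjusted p = 1.87e-11), and the kinase AKT1 fell 1.96-fold (-0.97 ± 0.12, adjusted p = 3.3e-05; -0.95 on its second probe). SELENOT and NETO2 fell by 0.96 ± 0.13 and 0.80 ± 0.08. The receptor NOTCH3 fell by 0.90 ± 0.19 (above background on 3 of 6 exon 7 arrays), while TNFAIP2 fell by 0.99 ± 0.22 (adjusted p = 0.0134; 0.0645 when the 2 groups were fitted alone). ANO8 fell by 1.02 ± 0.24 (adjusted p = 0.0202). Its call was lost without control replicate 1 (adjusted p = 0.0502) and when the 2 groups were fitted alone (adjusted p = 0.0513). CSRNP1 fell by 0.85 ± 0.20 (adjusted p = 0.0255) and lost its call without control replicate 2 or 4 (adjusted p = 0.0786 and 0.0636) or exon 7 replicate 1 or 5 (adjusted p = 0.0524 and 0.0706). PTPMT1 rose 2.62-fold (1.39 ± 0.11, adjusted p = 2.16e-08) and RBPJ, the DNA-binding partner of Notch, 2.51-fold (1.33 ± 0.11, adjusted p = 2.27e-08). LZTFL1 rose 2.72-fold (1.44 ± 0.18). WSB1 rose by 1.10 ± 0.15, CCND3 by 1.06 ± 0.10, the DNA methyltransferase DNMT3B by 1.06 ± 0.12 (0.39 and 0.51 on other probes), the receptor tyrosine kinase MET by 0.97 ± 0.12 and ERCC5 by 0.96 ± 0.15.

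Few members of the fixed groups changed singly under the exon 7 siRNA. Of 32 interferon genes 0 passed limma (1 at an unadjusted p below 0.05, 0 over the list alone), with a list median of -0.17 (adjusted p = 0.0359), medians of -0.48 and 0.10 in the column sets, and adjusted p = 0.986 with an estimated correlation. Of 28 S phase genes 1 rose, E2F2 by 0.52 ± 0.11 (1 over the list alone), a call lost under median scaling (adjusted p = 0.0620). This list had adjusted p = 0.0435, and adjusted p = 0.645 with an estimated correlation. By limma 0 of 34 mitotic genes passed (2 at an unadjusted p below 0.05; 0 over the list alone), with a median of 0.06 (adjusted p = 0.0435, and adjusted p = 0.835 with an estimated correlation). Among autophagy and lysosome genes limma called 0 of 28 (3 at an unadjusted p below 0.05; 2 over the list alone), with adjusted p = 0.0435, and adjusted p = 0.613 with an estimated correlation. Of 15 glucocorticoid targets limma called 0 (3 at an unadjusted p below 0.05; 0 over the list alone), with adjusted p = 0.0337, and adjusted p = 0.470 with an estimated correlation. In all, 212 genes changed under the exon 7 siRNA, 126 higher and 86 lower. With the column set as a block 252 changed, and within the sets 24 and 10 did. Median scaling called 124, of which 56 were higher and 68 lower, so the excess of rises depended on the scaling, and a fit on the arrays of the 2 groups alone also called 124.

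Under the exon 9 siRNA FGF2, a fibroblast growth factor, fell 3.84-fold (-1.94 ± 0.13, adjusted p = 6.92e-10; above background on 3 of 6 exon 9 arrays), although its second probe gave -0.44. TP53BP2 fell 2.16-fold (-1.11 ± 0.08, adjusted p = 1.96e-09; -0.04 on its second probe) and the cytokine IL6 2.01-fold (-1.01 ± 0.18, adjusted p = 0.00138). The growth kinase MTOR fell 1.86-fold (-0.89 ± 0.12, adjusted p = 2.3e-05). The cell cycle genes CDK6 and CCND2 fell by 0.97 ± 0.15 and 0.90 ± 0.11 (-0.97 on the second CCND2 probe), and SFTA1P and ENPP4 fell by 1.01 ± 0.18 and 0.96 ± 0.13. LZTFL1, PTPMT1, RBPJ and WSB1 rose by 1.55 ± 0.18, 1.37 ± 0.11, 1.15 ± 0.11 and 1.14 ± 0.15, the Polycomb cofactor JARID2 by 1.08 ± 0.10 and the RNA-binding MSI2 by 1.05 ± 0.12. The secreted ligand WNT5A was at least 1.96-fold higher (adjusted p = 0.000445), above background on 6 exon 9 arrays and 0 control arrays. IRX3 rose by 1.24 ± 0.30 (adjusted p = 0.0184), a call lost without exon 9 replicate 1 (adjusted p = 0.0578) or control replicate 4 (adjusted p = 0.0510).

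Of 22 NF-kB and inflammatory genes 4 fell under the exon 9 siRNA (7 over the list alone), with a median of -0.27 (-0.26 and -0.31 in the column sets). IL6 and the cytokine IL32 (-0.43 ± 0.09) fell, as did CCL5 (-0.60 ± 0.13; -0.11 on a second probe, and adjusted p = 0.213 when probes were averaged). The list passed camera (adjusted p = 7.25e-06) and held at adjusted p = 0.0381 with an estimated correlation. Falls were not particular to exon 9: under exon 1, 5 members fell and 1 rose (median -0.03, adjusted p = 0.313 by camera). Between siRNAs the list was lower under exon 9 than under exons 1 and 7 by camera (adjusted p = 0.0352 and 0.0137). With an estimated correlation these gave adjusted p = 0.345 and 0.327. Of 32 interferon response genes 3 fell (4 over the list alone), with a median of -0.40 (-0.22 and -0.69 in the column sets; adjusted p = 2.73e-07, and adjusted p = 0.662 with an estimated correlation). IFIT2 fell by 0.87 ± 0.17 (adjusted p = 0.00244) and IRF1 fell by 0.33 ± 0.09 (adjusted p = 0.0411), but the IRF1 call was lost with any of 10 of the 12 arrays left out (adjusted p up to 0.0991), under median scaling (0.117) and without the detection filter (0.0628). Of 34 mitotic genes 6 fell (7 over the list alone; median -0.12, adjusted p = 9.33e-07), CCNA2 (-0.35 ± 0.06) and PTTG1 (-0.38 ± 0.07) among them. The list gave adjusted p = 0.296 with an estimated correlation. Of 28 S phase genes 3 rose (3 over the list alone; adjusted p = 0.0337), E2F2 by 0.53 ± 0.11 and CCNE1 by 0.70 ± 0.13 (0.16 on a second probe). The S phase list gave adjusted p = 0.641 with an estimated correlation. Of 15 mesenchymal markers 3 rose, SNAI2 and TWIST1 by 0.50 ± 0.10 and 0.52 ± 0.12 and LOX at least 1.48-fold (6 over the list alone; median 0.26, adjusted p = 0.000881). That list gave adjusted p = 0.0993 with an estimated correlation. Of 20 epithelial adhesion genes 1 fell, MAL2 at -0.38 ± 0.08 (3 over the list alone; adjusted p = 0.00350, and adjusted p = 0.643 with an estimated correlation). Of 15 glucocorticoid targets 2 rose, SGK1 by 0.96 ± 0.15 and TSC22D3 by 0.47 ± 0.08 (3 over the list alone; adjusted p = 0.00310). As a set these gave adjusted p = 0.192 with an estimated correlation. With 1 array left out, 3 to 6 NF-kB, 1 to 4 interferon and 4 to 6 mitotic genes fell. In all, 400 genes changed under the exon 9 siRNA, 216 higher and 184 lower. With the column set as a block 470 changed, and within the sets 62 and 38 did. Median scaling called 251.

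**Figure D2:**
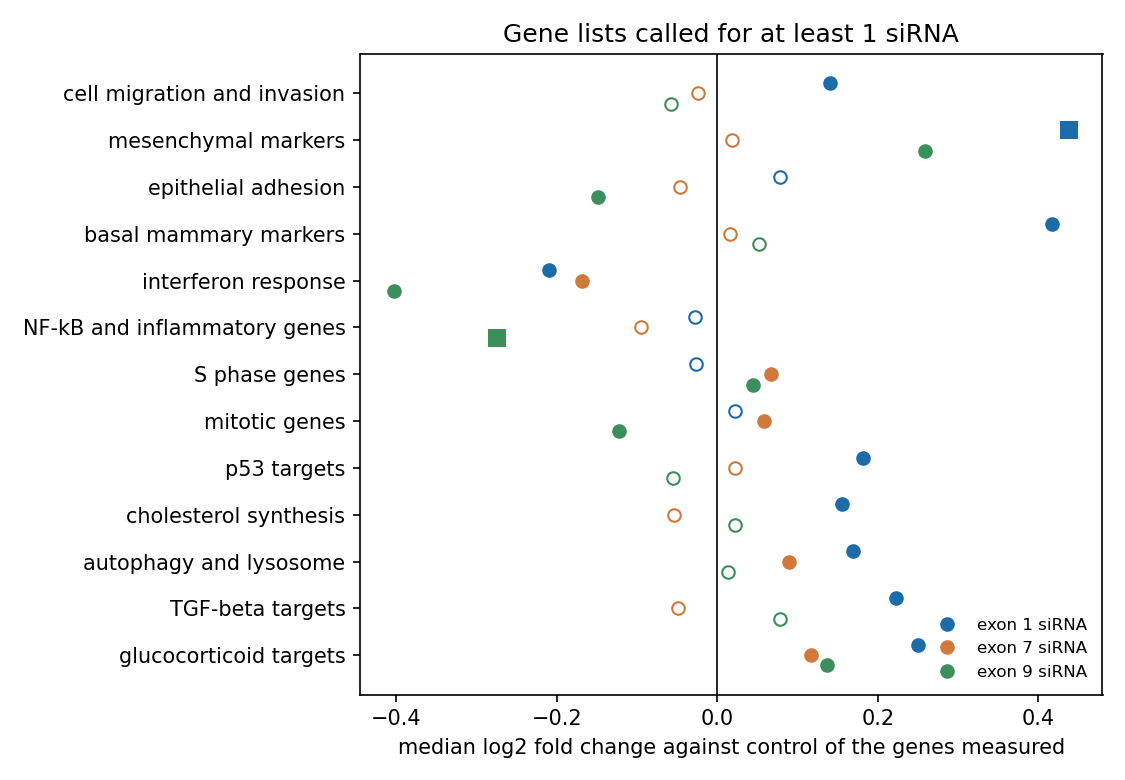
Median log2 fold change of each of the 13 lists that passed camera for at least 1 siRNA, for each siRNA against control. Filled marks passed camera at an adjusted p below 0.05, squares also did so with an estimated correlation, and open marks did not pass; the squares are mesenchymal markers under exon 1 (0.44) and NF-kB and inflammatory genes under exon 9 (-0.27).

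Across the 84 list tests 21 passed camera, 15 towards higher and 6 towards lower values, and 2 held with an estimated correlation. For interferon and mitotic genes under exon 9 and glucocorticoid targets under exons 1 and 9, that loss did not occur once the replicate number entered the fit, as the alternatives show. For these 21 the median, the mean and the test had the same sign, while in some lists that did not pass they differed, as for mesenchymal markers under exon 7 (median 0.02, mean -0.02). The other 15 lists passed for no siRNA, the smallest adjusted p being 0.0855 for immune cell markers under exon 9. They were the locus neighbours, MET signalling, luminal mammary markers, the unfolded protein and ATF4 response, hypoxia and glycolysis, RAS-MAPK output, YAP-TEAD targets, RNA interference machinery, heat shock, oxidative stress, cytosolic ribosomal proteins, oxidative phosphorylation, and the fibroblast, immune and adipocyte markers. Endothelial markers had fewer than 3 genes tested. With the replicate number as a block, camera also passed immune cell markers under exon 9 and NF-kB genes under exon 7 (adjusted p = 0.0227 for each). With an estimated correlation as well, these gave adjusted p = 0.101 and 0.159. In MET signalling, a theme of the published account and so not independent, MET rose under all 3 siRNAs and GRB2 (-0.55 ± 0.11; -0.40 on a second probe) and RAPGEF1 (-0.53 ± 0.12) fell under exon 1. A second RAPGEF1 probe gave 0.08, and its call was lost when probes were averaged (adjusted p = 0.191). The list gave adjusted p = 0.245, 0.961 and 0.570 under exons 1, 7 and 9, with 3, 1 and 1 members up and 2, 2 and 0 down over the list alone. For the fibroblast, 3 immune and 4 adipocyte markers measured, the list medians under exon 1 were 0.16, -0.03 and -0.09.

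A further question was which genes all 3 siRNAs changed alike. There were 57 genes higher and 6 lower under all 3, where independent lists of these sizes would share 0.128 and 0.0702. Unchanged groups set against the same controls shared 0 in the highest of 100 simulations. Those draws leave out the effects of the siRNAs, so they give no chance value for lists of these sizes. LZTFL1 (gene number 54585) rose by 1.72, 1.44 and 1.55 under exons 1, 7 and 9, and PTPMT1 by 1.25, 1.39 and 1.37. RBPJ rose by 1.22, 1.33 and 1.15, and WSB1 by 1.43, 1.10 and 1.14. CCND3 rose by 1.28, 1.06 and 1.03, and the DNA repair nuclease ERCC5 by 1.01, 0.96 and 0.98. MET rose by 0.94 ± 0.12, 0.97 ± 0.12 and 0.93 ± 0.12 (adjusted p = 1.21e-05, 2.52e-05 and 2.5e-05), and the stress kinase kinase MAP2K4 by 0.85, 0.80 and 0.83. The 6 that fell were smaller changes: ASMTL at -0.38, -0.56 and -0.68, RGS20 at -0.38, -0.36 and -0.38, and CTSC at -0.71, -0.40 and -0.35. HES4 lay at -0.33, -0.33 and -0.64, REPIN1 at -0.29, -0.31 and -0.33, and PNO1 at -0.41, -0.32 and -0.29. Each of these 6 lost a call in at least 1 comparison when any of several arrays was left out (adjusted p up to 0.126, 0.115, 0.120, 0.133, 0.0688 and 0.107 in that order), and other CTSC probes gave 0.49, 0.20 and -0.73 under exon 1. CTSC passed for no siRNA when its probes were averaged (adjusted p = 0.162, 0.290 and 0.492). Of the 63 shared genes 12 differed between any 2 siRNAs. Within the column sets 17 and 5 genes were shared, all of them higher, and median scaling called 41 (40 higher and 1 lower).

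**Figure D3:**
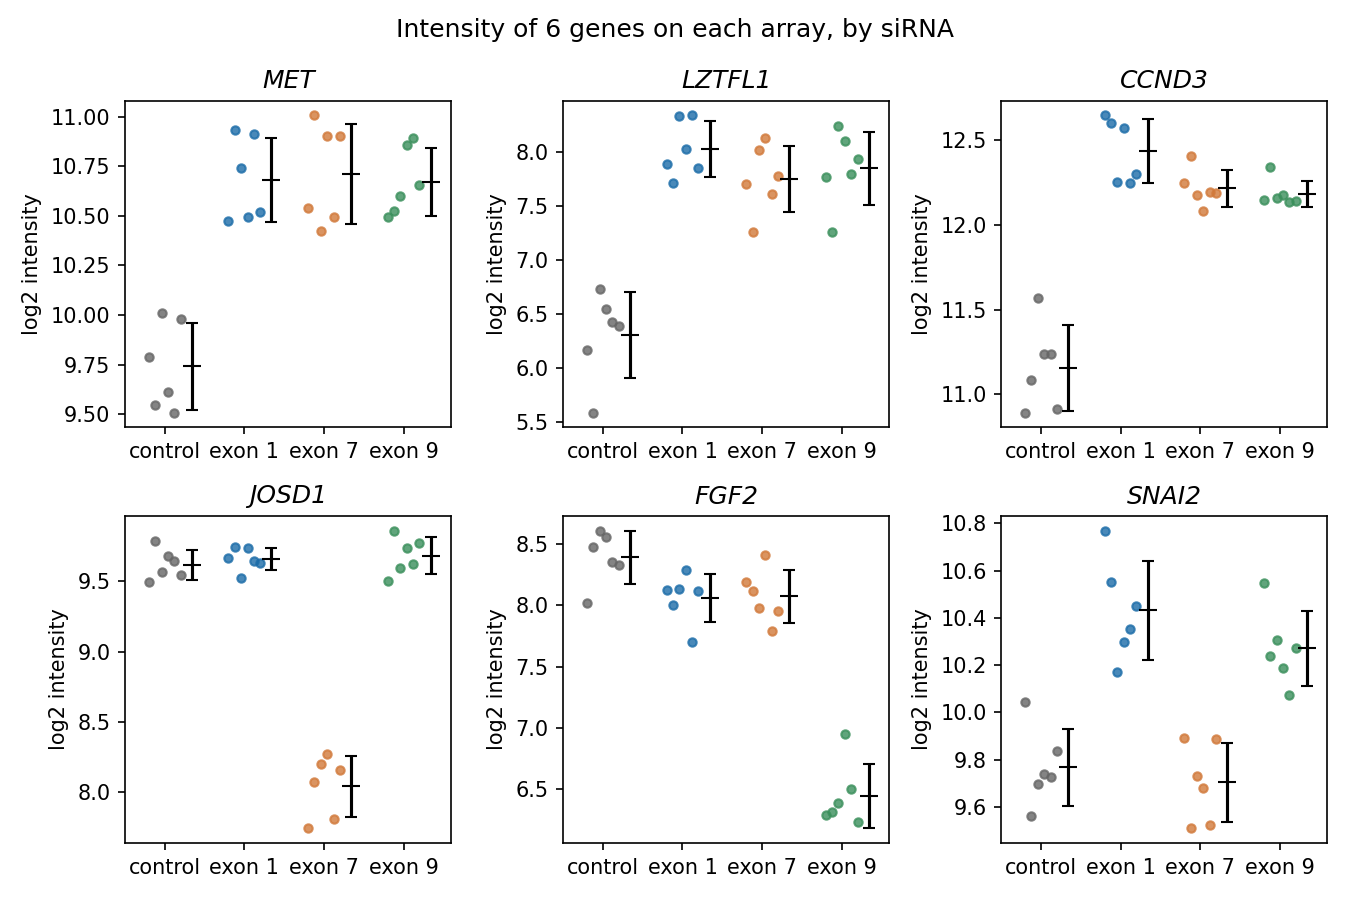
Normalized log2 intensity of MET, LZTFL1, CCND3, JOSD1, FGF2 and SNAI2 on each array, with the mean and SD of the 6 arrays per group. MET, LZTFL1 and CCND3 were higher under all 3 siRNAs, JOSD1 lower under exon 7 (-1.57), FGF2 lower under exon 9 (-1.94), and SNAI2 higher under exons 1 and 9 (0.66 and 0.50).

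Across genes, which are not independent replicates, the fold changes of exons 1 and 7 correlated at r = 0.34 (Spearman 0.31), those of exons 1 and 9 at r = 0.46 (0.42) and those of exons 7 and 9 at r = 0.46 (0.41). Unchanged groups set against shared controls gave mean r of 0.47, 0.50 and 0.50, so r itself does not separate the siRNAs from sampling of the controls. With separate controls r lay between 0.06 and 0.17, 0.18 and 0.29, and 0.16 and 0.17. Genes higher in both numbered 75 for exons 1 and 7, 130 for exons 1 and 9 and 66 for exons 7 and 9, against 6.54, 11.2 and 2.47 for independent lists. Genes lower in both numbered 13, 53 and 8, against 4.20, 8.98 and 1.44. Independent lists leave out the shared controls: unchanged groups set against them shared at most 0, 0 and 1 higher genes and at most 0 lower genes in 100 draws, which leaves out the effects. In opposite directions 5, 9 and 2 genes were called. The covariance of the fold changes was 0.0139, 0.0210 and 0.0151, where unchanged groups gave means of 0.00967, 0.0105 and 0.0104 and at most 0.0321, 0.0256 and 0.0250.

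The siRNAs were then compared directly, since siRNAs against different exons of 1 transcript would be set side by side to tell effects that differ between them. JOSD1 was lower under exon 7 than under exon 1 (difference 1.61 ± 0.09 for exon 1 minus exon 7, adjusted p = 1.09e-11) and than under exon 9 (-1.64 ± 0.09 for exon 7 minus exon 9, adjusted p = 7.6e-12). FGF2 was lower under exon 9 than under exon 1 (1.61 ± 0.13 for exon 1 minus exon 9, adjusted p = 9.17e-09) and than under exon 7 (1.62 ± 0.13, adjusted p = 1.05e-08). FAM117B was lower under exon 1 than under exon 7 (-1.33 ± 0.12) and exon 9 (-1.92 ± 0.12, adjusted p = 1.43e-10), as was MED11 (-1.41 ± 0.16 and -1.36 ± 0.16). Between exons 1 and 7, ZNF365 (1.40 ± 0.20) and the keratin KRT6C (1.25 ± 0.22) were higher under exon 1, as were SPOCD1 (at least 1.32-fold) and the collagen COL5A2 (at least 1.27-fold). There SNORD13 (-1.64 ± 0.17), SCML1 (-1.43 ± 0.15) and the prostaglandin transporter SLCO2A1 (-1.31 ± 0.17) were lower. Between exons 1 and 9, KRT6C (1.41 ± 0.22), KATNAL1 (1.20 ± 0.21), the acetyltransferase KAT2B (1.20 ± 0.18) and PGM2L1 (1.18 ± 0.27) were higher under exon 1. The cyclin CCNE1 (-1.32 ± 0.13), RNU4-1 (at least 2.22-fold) and HOMER1 (at least 1.54-fold) were lower. Between exons 7 and 9, AVL9 (1.25 ± 0.12), CCND2 (1.09 ± 0.11), TP53BP2 (1.08 ± 0.08) and ADAM8 (1.00 ± 0.13) were higher under exon 7. SMAP1 (-1.22 ± 0.14; above background on 4 of 6 exon 7 arrays), WNT5A (-1.07 ± 0.21), RNU4-2 (2.00-fold) and RNU4-1 (-1.11 ± 0.27) were lower. For several of these genes a second probe changed less or not at all. Against control, the second probe gave 0.58 under exon 7 and 0.48 under exon 9 for SMAP1, 0.04 under exon 1 and 0.16 under exon 9 for CCNE1, and 0.16, -0.02 and -0.44 under exons 1, 7 and 9 for FGF2. It gave 0.29 under exon 7 and -0.04 under exon 9 for TP53BP2, 0.18 and -0.43 for AVL9, -0.33 under exon 1 and -0.14 under exon 7 for SCML1, and -0.80, -0.06 and 0.32 under exons 1, 7 and 9 for FAM117B. RNU4-1, above background on 2 exon 1, 4 exon 7 and 5 exon 9 arrays, lost its call between exons 7 and 9 without exon 9 replicate 1 (adjusted p = 0.0593) and when the 2 groups were fitted alone (adjusted p = 0.0536). Mesenchymal markers were higher under exon 1 than under exon 7 (median difference 0.50, adjusted p = 1.45e-07, and adjusted p = 0.00858 with an estimated correlation) and lower under exon 7 than under exon 9 (-0.18, adjusted p = 4.48e-05, and adjusted p = 0.0398 with an estimated correlation), in tests added after the data were seen.

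Between exons 1 and 7, 1273 genes differed (662 higher under exon 1 and 611 lower), with 1460 under the column set block, and 300 and 131 within the sets. Median scaling split them into 743 higher and 294 lower. Between exons 1 and 9, 925 differed (476 and 449), with 1090 under the block, and 191 and 41 within the sets. Median scaling called 607, and 613 were called without exon 1 replicate 2. Between exons 7 and 9, 464 differed (245 and 219), with 545 under the block, and 12 and 36 within the sets. Median scaling called 271, 71 higher and 200 lower. Over all genes, which are not independent replicates, fold changes in the 2 sets correlated at r = 0.60, 0.21 and 0.33 for exons 1, 7 and 9 against control, and at 0.52, 0.53 and 0.19 for the 3 comparisons between siRNAs in the order above.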

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

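The permutation of the interferon means over all 12 arrays was chosen before its result was seen, and the one within replicate numbers was added afterwards. In 576 groups of 6 arrays, over named genes and array measures, 35 groups (6.08%) had 1 array far from the other 5. Chance flags about 1 in 20 groups, which would be 28.8 here.

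Control replicate 2 was far above the other control arrays for KATNAL1 (7.65), IFIT2 (12.13), IFIT3 (11.23) and ISG20 (9.95). Exon 1 replicate 2 was far above its group for IFIT3 (10.49), IFI44 (9.54) and RHOB (9.90), and exon 7 replicate 2 for IFIT3 (10.37). Other arrays far above their group were exon 9 replicate 5 for MMP9 (6.67) and SPOCD1 (6.18), exon 9 replicate 2 for CCND3 (12.34), exon 9 replicate 3 for NOTCH3 (7.20), exon 9 replicate 4 for GADD45A (10.36), control replicate 1 for CTSC (10.59), exon 1 replicate 5 for INSL5 (7.32), exon 1 replicate 1 for ANKRD13C-DT (7.44) and IL32 (9.69), and exon 7 replicate 4 for TAGLN (8.31). Control replicate 5 had the highest share of probes above background in its group (39.2%).

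Far below their group lay exon 7 replicate 4 for IRX3 (6.54) and IFIT5 (6.54), control replicate 3 for PLEKHA3 (6.45), GNG12 (7.81) and MYL9 (6.96), and exon 1 replicate 3 for ANO8 (6.51). The same held for exon 9 replicate 3 for NETO2 (10.62), exon 1 replicate 1 for WNT5A (5.29), exon 9 replicate 4 for REPIN1 (10.69), exon 7 replicate 2 for MIER1 (8.34) and exon 1 replicate 5 for OASL (7.14) and RAPGEF1 (8.48). It also held for exon 9 replicate 1 for LSS (9.82) and PTTG1 (12.07), exon 7 replicate 3 for DUSP1 (11.31) and exon 7 replicate 1 for NUSAP1 (11.44). Probes with no gene name, which no comparison of named genes used, also differed from control: 196 of 4846 under exon 1, 23 under exon 7 and 58 under exon 9.

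Interferon response genes had a median of -0.40 under the exon 9 siRNA against control. The mean of the list per array was highest on the replicate 2 array of every group (10.23 for control, 9.94 for exon 1, 9.97 for exon 7 and 9.75 for exon 9), and lowest on the replicate 5 array of every group, so the genes vary together by replicate number. An exact two-sided permutation of the 12 array means, 9.34 on average for control and 8.90 for exon 9, gave p = 0.143. That test counts the variation between numbers as noise. A permutation of the 4 groups within each number gave p = 2.00e-05 for the difference of -0.43 in 100000 draws. That permutation needs no view on what the number stands for. Control was highest of the 4 groups in 6 of 6 numbers, and exon 9 was lowest in 5 of 6. The same-number differences of exon 9 and control alone gave an exact sign-flip p = 0.0313. Thus the permutation chosen beforehand left variation between arrays open, while the tests within numbers, added afterwards, argued against it. An effect of the control siRNA alone would leave exon 9 level with exons 1 and 7. Exon 9 averaged 8.90, against 9.11 for exon 1 and 9.16 for exon 7, and was lowest in 5 of 6 numbers. Camera gave adjusted p = 0.00216 between exons 7 and 9 and 0.0642 between exons 1 and 9. With an estimated correlation these were 0.751 and 0.784. The order within numbers, not tested between siRNAs, argues against an effect of the control siRNA alone. How far such an effect adds to the difference of -0.43 cannot be told.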

How the results depend on the processing

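The column set block, the column sets alone, both blocks together, the replicate block with an estimated correlation and the same-number tests were chosen after seeing the data; the other alternatives were planned. No named gene value changed direction with a call under any alternative. The 21 list calls had 84 medians under no background correction, median scaling, cyclic loess and the authors' values, and 0 changed sign. Medians of lists that did not pass were not checked this way. The cause of the changes below was not tested except where the alternative itself gives it.

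The replicate numbers were not accepted as pairs, since 30 of 36 pairs of arrays correlated above 0.1 (lowest 0.04), although 22 of 24 arrays lay closest to an array of their own number. With the column set removed 35 of 36 pairs did (lowest 0.090) and 24 of 24 arrays lay closest to their own number. By the sample titles each replicate number stands for 1 experiment with 1 array of every group. The titles number most of these experiments differently and name no shared day or batch. Pairing is thus likely, but not every pair passed, and the fits without it were kept. Those fits count variation between numbers as noise. With the number as a block, 2061, 580 and 1030 genes changed under exons 1, 7 and 9, 2203, 1869 and 1069 differed between exons 1 and 7, 1 and 9, and 7 and 9, 157 were shared and 1 of the 33 locus tests passed. As a random effect (correlation 0.243) these were 1841, 479, 835, 2000, 1641, 889, 110 and 2, and with replicate and column set both as blocks 2523, 826, 1337, 2673, 2327, 1433, 207 and 3. Of the shared genes 45 of 157, 26 of 110 and 66 of 207 were lower in these 3 fits, against 6 of 63, so the excess of rises was smaller with the number in the fit. With the column set alone as a block 2 of the 33 locus tests passed, both of them WLS. Same-number differences of the interferon genes between exon 9 and control were all lower in 6 of 6 (-0.34 to -0.58; exact sign-flip p = 0.0313), and with the number as a block the list passed with an estimated correlation too (adjusted p = 0.0326), unlike without the block.

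Within column set 1, with 3 arrays per group, the 6 counts were 233, 24, 62, 300, 191 and 12 with 17 shared, and within set 2 they were 97, 10, 38, 131, 41 and 36 with 5 shared; fewer arrays give fewer calls. A 1.5-fold minimum, which removes small changes, left 290, 56, 110, 287, 229 and 94, with 21 shared. Fits of the 2 groups alone, with fewer arrays behind the spread, called 684 for exon 1 and 124 for exon 7. Median scaling called 124 for exon 7, 251 for exon 9, 607 between exons 1 and 9, 271 between exons 7 and 9 and 41 shared.

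With separate controls the correlations were 0.062 and 0.17 for exons 1 and 7, 0.18 and 0.29 for exons 1 and 9, and 0.16 and 0.17 for exons 7 and 9. There no control array is shared and each siRNA is set against fewer control arrays, and these changes were not separated. Of 21 list calls 2 held with an estimated correlation, 6 with the replicate block as well (gained: glucocorticoid targets under exons 1 and 9 at adjusted p = 0.0263 and 0.0398, mitotic and interferon genes under exon 9 at 0.0184 and 0.0326), and 9 under fry, which called 1 other, fibroblast markers under exon 1 (adjusted p = 0.0133). Leaving out 1 array gave 774 to 1265 genes for exon 1, 155 to 212 for exon 7, 288 to 404 for exon 9, 894 to 1509 between exons 1 and 7, 613 to 1105 between exons 1 and 9, 332 to 428 between exons 7 and 9, 51 to 66 shared and 0 to 1 locus tests. Of 227 named gene values 26 lost a call without some array and 10 gained one; signal near background limits KATNAL1, LZTFL1, MMP9, WNT5A and PLEKHA3.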

Other observations

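The tests of shared controls, of an effect of the control siRNA, of GNG12-AS1 loss, of unintended targets and of the splits of arrays for each comparison and for the shared genes were chosen after the results were seen; the test of noisier arrays and the splits for the exon 1 and exon 7 difference and for the lists were chosen before. Outside the lists of interest, mitotic genes were higher under exon 7 than under exon 9 (median difference 0.19, adjusted p = 8.23e-12, 8 members higher and 0 lower), and the adjusted p = 0.128 with an estimated correlation. Cholesterol synthesis genes were higher under exon 1 than under exon 7 (0.20, adjusted p = 0.00140, 4 members higher and 0 lower), and the adjusted p = 0.362 with an estimated correlation.

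In 100 splits of the 12 arrays of a comparison, the real one included, 1 of 100 gave as many genes, the real one, in all 6 comparisons. The real and the highest other count were 1108 and 711 for exon 1 against control, 212 and 203 for exon 7, 400 and 29 for exon 9, 1273 and 352 for exon 1 against exon 7, 925 and 60 for exon 1 against exon 9, and 464 and 36 for exon 7 against exon 9. For exon 7 the real count barely exceeded the highest other, so chance was not clearly excluded there. In the other comparisons no other split drawn reached the real count. The splits were a random part of those possible and crossed replicate numbers. Only the highest other split was looked at, so whether a split by column set was drawn there is not known. The split that gave 203 genes parted the exon 7 and control arrays exactly by column set, which points to a structure of the samples; with the column set as a block exon 7 changed 252 genes, and within the sets 24 and 10. For the 63 genes shared by all 3 siRNAs, 2 of 100 regroupings of the 24 arrays gave as many, the real one and 1 other with 81. As many genes were thus rare, but a random regrouping exceeded the real count. The regrouped arrays keep the effects of the siRNAs and the column sets, so they are not draws without effects. The test therefore does not decide on chance for the number of shared genes. For the 21 list calls, 6 of 100 regroupings gave as many, the highest other 32, so chance cannot be excluded for their number. The regroupings of the 24 arrays crossed replicate numbers and so count variation between numbers as noise. Regroupings within numbers were not run for the shared genes or the lists.

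All 3 siRNAs raised 57 genes alike and lowered 6, an imbalance that shrank with the replicate number in the fit (45 lower of 157). With no siRNA effect, sampling error of the shared controls gave at most 0 such genes in 100 simulated draws. The draws leave out the effects, so how far that error adds to the count beside them cannot be told. An effect of the control siRNA itself stays open: the genes that set the control apart from all 3 siRNAs are these same 57 and 6, so the 90.5% of them that were lower in the control restate the direction and decide nothing. Loss of the GNG12-AS1 RNA stays open too and cannot be told apart from it, because 0 probes were named GNG12-AS1.

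The exon 1 siRNA changed 896 more genes than the exon 7 siRNA, and 1 of 100 splits of their 12 arrays gave as large a difference, the real one, the highest other being 613. Noisier exon 1 arrays would not give this, since the covariance of fold changes between separate subsets of the arrays was larger for exon 1 in every such division (0.0358 to 0.0454) than for exon 7 (0.00912 to 0.0180), the lowest exceeding the highest by 0.0178. More unintended targets of the exon 1 siRNA cannot be told from these arrays, since 65.6% of the genes that set exon 1 apart from the other groups were lower, with 64.4% for exon 7 and 74.4% for exon 9, and the share does not set exon 1 apart. A difference in the effect of the exons themselves stays open and was not tested.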
